A study of Mus musculus with 24 samples.

How the data were processed

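RNA of pineal glands and retinas of C57BL/6J mice was measured on Affymetrix Mouse 430 2.0 arrays, per the series' design text. Control mice had floxed Neurod1 alleles and no Cre, and cKO mice had the same alleles with a Crx-Cre transgene, per the labels. Tissue was collected at ZT6 and at ZT20, the latter under dim red light, and 6 glands or retinas were pooled for each array, per the labels' protocols. RNA was isolated with the RNeasy Micro kit and amplified and labelled with the NuGEN Ovation V2 and FL-Ovation biotin kits, per the labels' protocols. The groups were taken from the sample titles, and every pool was counted as 1 replicate.

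The deposited values are linear signal intensities, 1 per probe set and array, with 45101 probe sets and no value below 0. GCOS is named in the submitters' processing notes, and the sources used here give no version, array scaling, detection calls or filter. The 2 to 98 percent trimmed means ran from 549 to 722 in the pineal gland and from 535 to 765 in the retina. Thus no common trimmed mean had been set. Arrays of one group correlated at r = 0.983 to 0.992 across probe sets. At most 0.494% of values were identical in any of the 276 pairs, so no array had been deposited more than once. Log2 ratios of 3' to 5' control probe sets in the pineal gland were 0.36 to 0.51 for Gapdh and 1.07 to 1.50 for Actb. In the retina they were 0.26 to 0.52 and 1.11 to 1.79. The number of arrays limits the precision. No scan date was used here, so batches of arrays could not be examined.

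Probe sets were named from the platform annotation: 34945 had 1 gene symbol (18193 genes), 932 had several and 9224 had none in the table used, and the latter were left out, as were 64 control probe sets. Gene identifiers of 34741 probe sets were matched to current RefSeq symbols, and 0 symbols changed. A gene was represented by the probe set with the highest mean over the 24 arrays, avoiding cross-hybridising sets (suffix _x_at) unless a gene had no other. Signals were converted to log2(value + 16), so that fold changes of dim genes are understated, and were not normalised further in the main setting. A gene was tested in a tissue if it lay above the median of the array on at least 3 of the 12 arrays, which left 11936 genes in the pineal gland, 11696 in the retina and 12866 in fits across tissues.

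Each tissue was fitted with limma 3.58.1 in R 4.3.3 (lmFit, then eBayes with a mean-variance trend), with 1 mean for each of its 4 groups, and comparisons across tissues were fitted with all 8 groups and 24 arrays. There were 14 comparisons: cKO against control at ZT6, at ZT20 and averaged over both, ZT20 against ZT6 in each genotype and the difference of these, in each tissue, then the cKO effect in retina against pineal gland and control retina against control pineal gland. P-values are two-sided and adjusted by Benjamini-Hochberg over the genes tested in a comparison, with a threshold of 0.05. With 3 pools against 3, an exact permutation test of a single gene cannot give a p under 0.1, and chance leaves the pools of 10% of unchanged genes without overlap. The prior degrees of freedom of the pineal fit were 157.2, against 6.8 on quantile-normalised values and 7.2 without the variance trend, beside 8 residual ones, so that its p-values lean on a spread shared by all genes. In the retina they were 9.1, 5.4 and 3.9, and in the fit of both tissues 12.9, 5.8 and 4.8.

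Of 30 gene lists of cell types, pathways and complexes, 498 members were matched to genes of the arrays and 53 were not. Lists with at least 5 tested members were tested with camera at a preset inter-gene correlation of 0.01, adjusted over the lists of a comparison, and again with an estimated correlation and with fry. Of 386 such tests 141 passed by camera, 82 by fry and 3 with an estimated correlation, namely the cAMP-responsive list between day and night in the cKO pineal gland and the reactive gliosis and microglia lists in the cKO effect between tissues. These 30 lists, the tests, the rule for named genes and the alternatives that are not said to be added were fixed before the data were examined. The rule named Neurod1 in every group, the 10 largest rises and falls among genes that passed and whose pools did not overlap for the 4 genotype comparisons at 1 time and both control day-night comparisons, and 5 each way for the others, passing over clones, predicted genes and sex-linked genes. Of each list described it named up to 4 called members with the largest changes or, where none passed, up to 2 with the highest mean, and 12 genes fixed by name (Crx, Otx2, Tph1, Aanat, Gnat1, Opn1sw, Opn1mw, Sag, Gfap, Prkca, Per1 and Dbp), of which a few are left out of the shorter comparisons. 3 lists of neutrophil and marrow, bone and osteoclast, and mast cell genes were written after the values had been seen.

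The labels number the pools of each group from 1 to 3 without saying whether a number is shared. Deviations from group means of same-numbered pools correlated at r = 0.226 to 0.418 between control and cKO pineal glands at ZT6, where every pair was over 0.1, and by this measure the numbers pair these pools. In none of the other pairs of groups were all 3 correlations over 0.1.

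The steps were tested on simulated data, with 200 changed genes drawn on the arrays of 1 comparison. For the pineal gland at ZT6 (11936 genes), 24.2, 83.6 and 100% of genes changed by a log2 of 0.5, 1 and 2 were recovered and 4% of 150 calls were unchanged genes. For the retina at ZT6 (11696 genes) these were 22.7, 70.1 and 98.5%, and 8.39% of 143 calls. A list of raised genes was called in both, and 0 and 1 of 20 random lists were. The simulated noise lacked gene correlation and array brightness.

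The alternatives were a pseudocount of 1 or 64, median centring, quantile and cyclic loess normalisation, no filter or one at the array's 75th percentile, no variance trend, a robust variance model, array weights, only the groups compared, the pool number as a block, the probe set of largest variance, calls of at least 2-fold, and each array left out in turn. Added after seeing the data were trimmed-mean scaling, leaving out the cKO ZT20 pools 2 and 3 (alone and with quantile normalisation), leaving out the pineal ZT6 pools 3, and the block in the 6 pineal ZT6 arrays alone. Where a group was left with 1 pool, that pool was assumed to vary like those of the other groups. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.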

Results

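Neurod1 encodes a basic helix-loop-helix (bHLH) transcription factor found in photoreceptors, pinealocytes, other neurons and pancreatic islet cells. The series asked what its loss changes in the pineal gland and the retina by day and by night. Conditional knockout mice (cKO) carried floxed Neurod1 alleles and Cre under the promoter of Crx, a gene of photoreceptors and pinealocytes, and controls the alleles alone. Glands and retinas of mice of both sexes, 2 months old, were taken 6 h (ZT6, day) and 20 h (ZT20, night) after lights on, in a cycle of 12 h light and 12 h dark. Each of the 8 groups of tissue, genotype and time had 3 pools of 6 glands or retinas, each on 1 of 24 arrays. A p-value therefore measures the spread between pools, not between single mice. Array medians ran from 107.1 to 158.8 units in the pineal gland and 107.8 to 183.1 in the retina. In the pineal gland cKO group medians were lower, 122 ± 8.32 (SD) at ZT6 and 115 ± 12.6 at ZT20. Controls had 145 ± 14.5 and 145 ± 12.1. Trimmed means were 673 and 622 in cKO against 671 and 688, so at ZT6 only the medians were lower. In the retina cKO medians were higher, 153 ± 26.4 and 148 ± 20.5 against 119 ± 8.72 and 125 ± 15.7. Each count of genes is therefore given also after median centring and quantile normalisation, and medians of gene lists are relative to that of all genes tested. Changes are log2 differences ± SE from limma with n = 3 pools per group, and "passed" means an adjusted p under 0.05.

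The target of the knockout comes first. In the pineal gland the Neurod1 signal was 4974 ± 312 (SD, n = 3 pools) in controls at ZT6, and 83.5, 29.1 and 30.9 in the 3 cKO pools. At ZT20 the control pools averaged 3622 ± 618 and the cKO pools read 22.5, 1897 and 960, which is 0.621, 52.4 and 26.5% of the control mean. In the retina the signal was 6407 ± 646 in controls against 639, 774 and 293 in cKO at ZT6, and 7237 ± 480 against 369, 3595 and 3582 at ZT20. Pools 2 and 3 labelled cKO at ZT20 kept 49.7 and 49.5% of the control signal. A second Neurod1 probe set gave 42.1 and 20.1% in these pineal pools and 34.6 and 34.3% in the retinal ones. Neurod1 fell in cKO at ZT6 (pineal gland -6.39 ± 0.34, adjusted p = 1.6e-39, retina -3.56 ± 0.57, adjusted p = 4.5e-04) and at ZT20 (pineal gland -3.12 ± 0.34, adjusted p = 9.8e-13, retina -2.08 ± 0.57, adjusted p = 0.035). On quantile-normalised values the pineal fall at ZT20 was about as large, -3.01 ± 0.90, but did not pass (adjusted p = 0.31). Its SE there rests on 6.8 prior degrees of freedom in place of 157.2, so that each gene's own spread weighs more. After median centring it was -2.82 ± 0.79 (adjusted p = 0.071). The retinal fall at ZT20 did not pass when control ZT20 pool 1, 2 or 3 was left out (adjusted p 0.06, 0.09 and 0.11). Which part of the gene the floxed alleles remove is not given in the sources used here.

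**Figure D1:**
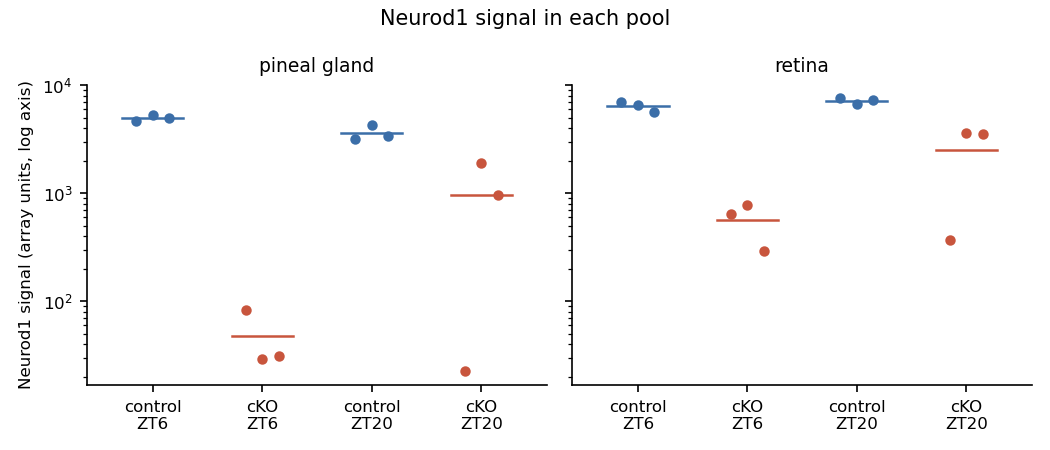
Neurod1 signal of every pool (points, log axis, array units) with the group mean (line), control in blue and cKO in red. All ZT6 cKO pools lie far below their controls, and pools 2 and 3 labelled cKO at ZT20 lie between, at 1897 and 960 in the pineal gland and 3595 and 3582 in the retina.

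The first comparison asked what differed in the pineal gland by day. Transcripts of the pinealocyte itself did not pass the test apart from Neurod1: Crx, the homeobox factor of photoreceptors and pinealocytes, was at 0.04 ± 0.07, and Otx2, a homeobox factor upstream of it, at 0.05 ± 0.09. Tph1, the first enzyme of melatonin synthesis from tryptophan, was at 0.02 ± 0.06, Aanat, its night-driven N-acetyltransferase, at 0.19 ± 0.18, and Sag, the arrestin of rods and pinealocytes, at 0.03 ± 0.07. After median centring Crx (0.27, adjusted p = 0.022), Otx2 (0.28, adjusted p = 0.015), Tph1 (0.25, adjusted p = 0.026) and Sag (0.26, adjusted p = 0.015) passed as higher in cKO, by about the shift of all genes. Of the list of pinealocyte and melatonin genes 0 of 23 members passed the test (0 adjusted over the list alone, camera adjusted p = 0.47). The largest falls besides Neurod1 were in the collagenase Mmp13 (-2.31 ± 0.26, adjusted p = 3.8e-12), bone sialoprotein Ibsp (-2.15 ± 0.32, adjusted p = 6.8e-07) and the neutrophil calcium-binding protein S100a8 (-2.07 ± 0.23, adjusted p = 3.0e-12). Next were Tbrg3 (-1.76), Slfn4 (-1.66), S100a9 (-1.64), the antimicrobial peptide Camp (-1.64), Chil3 (-1.52) and Rgs18 (-1.50). The largest rises were in the immunoglobulin light chain Iglv1 (2.87 ± 0.29, adjusted p = 1.1e-14) and the pre-B cell light chain Igll1 (1.78 ± 0.27, adjusted p = 1.1e-06). They were followed by the desmosomal Dsp (1.23 ± 0.22, adjusted p = 4.1e-05), Slc28a3 (1.15), Rbm47 (1.11), Elovl7 (1.08), the protease inhibitor A2m (1.07), the GABA receptor subunit Gabrb1 (1.06), Kl, which encodes Klotho (1.05 ± 0.16, adjusted p = 8.2e-07), and the carbonic anhydrase Car12 (1.04).

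Of the choroid plexus list 8 of 14 members rose and the others did not pass (12 higher adjusted over the list alone), with a median 0.61 above that of all genes (camera adjusted p = 3.0e-24, adjusted p = 0.25 with an estimated correlation). They included Kl, the tight junction protein Cldn2 (0.95), the folate receptor Folr1 (0.87) and Sostdc1 (0.86). Of microglia and macrophage genes 2 of 17 members fell (4 lower adjusted over the list alone, median -0.38, camera adjusted p = 1.2e-08, adjusted p = 0.75 with an estimated correlation), namely the signalling adaptor Tyrobp (-0.63) and lysozyme Lyz2 (-0.45). Of the fibroblast and meninges list 1 of 14 members rose and 2 fell (1 higher and 3 lower adjusted over the list alone, camera adjusted p = 0.0015, adjusted p = 0.97 with an estimated correlation), led by the organic anion transporter Slc22a6 (-1.25) and the collagen chain Col6a3 (-0.98). In 3 lists written after the values had been seen, 10 of 10 neutrophil and bone marrow genes, 6 of 8 bone and osteoclast genes and 4 of 6 mast cell genes fell, with medians of -1.41, -1.0 and -1.05. In the endothelium and mural cell list 0 of 15 members passed the test (0 adjusted over the list alone, camera adjusted p = 0.17). Of habenula and neighbouring brain neuron genes 1 of 5 members fell, the synaptic Nrgn (-1.03, 1 lower adjusted over the list alone, camera adjusted p = 0.28). Of 4 red blood cell genes 2 fell, the haem synthesis enzyme Alas2 (-1.11) and the globin Hbb-b2 (-0.46) (2 lower adjusted over the list alone). Of 4 sex-linked genes 1 fell (1 lower adjusted over the list alone). Both lists were too short for a set test. Of genes of ribosomal proteins, mitochondrial respiration, neuroendocrine and islet cells (linked to NEUROD1) and synapse and vesicle release 0 of 13, 21, 15 and 17 members passed (0 adjusted over the list alone in each, camera adjusted p = 0.18, 0.74, 0.71 and 0.58).

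In all, 234 of 11936 genes passed at ZT6, 89 higher and 145 lower in cKO. Centred on array medians the count was 4175, with 4021 higher and 154 lower, and on quantile-normalised values 227 (75 and 152), of which 99 were shared. The median of all genes was 0.03, 0.25 and 0.03 in these fits. Same-numbered pools of these groups deviated together. With the pool number as a block 293 genes passed in all 12 pineal arrays and 521 in these 6, against 508 in these 6 without it. Without control pool 1, control pool 3 or cKO pool 2 the count was 95 (5 higher, 90 lower), 120 (65 and 55) and 140 (47 and 93), and without cKO pool 3 93 were lower. It was 83 without pool 3 of both groups, in which the signal of the rod transducin Gnat1 was 3830 and 2234. The call on Tyrobp ended whichever pool was left out (adjusted p 0.064 to 0.29). Without control pool 1 calls ended on A2m, Car12, Cldn2, Elovl7, Folr1, Hbb-b2, Ibsp, Rbm47, Slc28a3 and Sostdc1 (adjusted p 0.063 to 0.15) and without pool 3 on Lyz2 and Nrgn (0.076 to 0.48). Without cKO pool 2 calls ended on Nrgn (adjusted p = 0.15) and without pool 3 on Col6a3, Hbb-b2, Lyz2 and Nrgn (0.086 to 0.38). Quantile normalisation ended calls on A2m, Camp, Car12, Chil3, Cldn2, Col6a3, Elovl7, Folr1, Hbb-b2, Ibsp, Kl, Mmp13, Nrgn, Rbm47, Slc28a3 and Sostdc1 (adjusted p 0.053 to 0.19). Most changes stayed close (Mmp13 -2.23, Kl 1.02, but Nrgn -0.80). After median centring the calls on Lyz2 (-0.22, adjusted p = 0.079) and Hbb-b2 (-0.23, adjusted p = 0.19) ended.

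**Figure D2:**
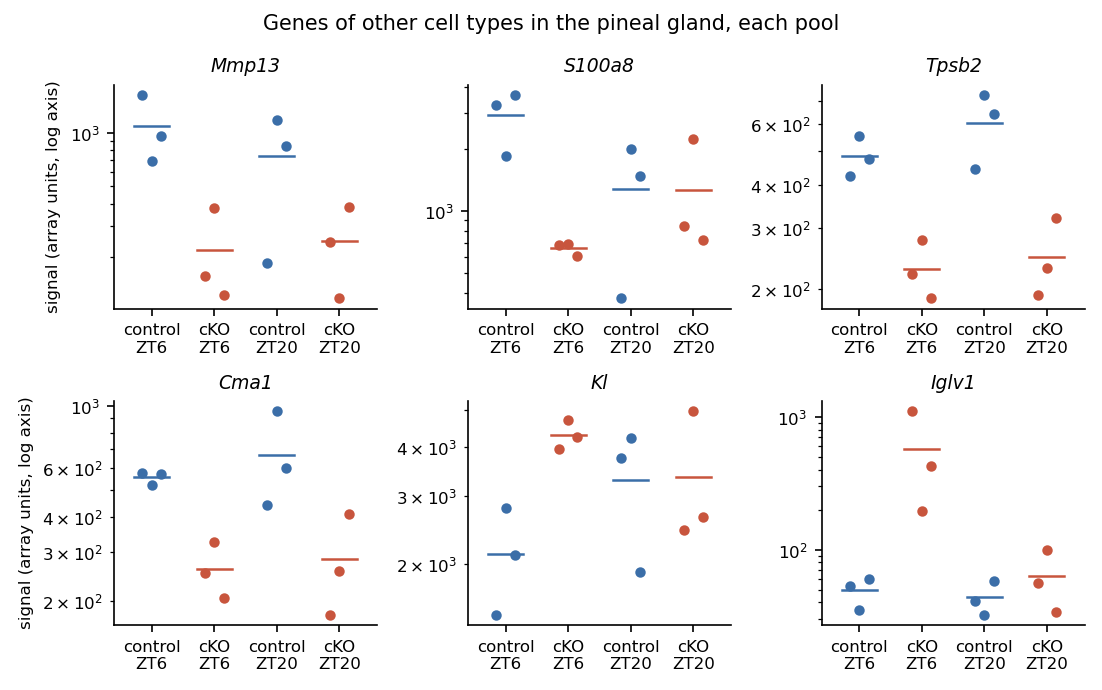
Signal of 6 genes of other cell types in every pineal pool (points, log axis, array units) with the group mean (line). Mmp13 and S100a8 are lower in the ZT6 cKO pools, Tpsb2 and Cma1 in the ZT20 cKO pools, and Kl and Iglv1 are higher in the ZT6 cKO pools.

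At night the pineal genotypes were compared in the same way. Besides Neurod1, the largest falls were in the macrophage lectin Mgl2 (-1.25 ± 0.23, adjusted p = 3.9e-04), tryptase Tpsb2 (-1.24 ± 0.21, adjusted p = 1.4e-04), chymase Cma1 (-1.20 ± 0.21, adjusted p = 2.8e-04), Sema3g (-1.18) and chymase Mcpt4 (-1.12). Next were Adamts12 (-1.11), the endothelial apelin receptor Aplnr (-1.09), Cyp2f2 (-1.07) and carboxypeptidase Cpa3 (-1.05). Tpsb2, Cma1, Mcpt4 and Cpa3 are genes of mast cells. Of the lists written after the values had been seen, 4 of 6 mast cell genes and 5 of 8 bone and osteoclast genes fell at ZT20 too (medians -1.09 and -0.81), but 1 of 10 neutrophil and bone marrow genes (-0.05). The gene that rose was Gad1 (1.16 ± 0.28, adjusted p = 0.016), which makes the transmitter GABA. Melatonin enzymes and pinealocyte factors lay near 0 (Tph1 0.00 ± 0.06, Aanat -0.08 ± 0.18, Crx -0.01 ± 0.07, Otx2 -0.01 ± 0.09). Of fibroblast and meninges genes 7 of 14 members fell (11 lower adjusted over the list alone), with a median -0.27 relative to all genes (camera adjusted p = 2.6e-18, adjusted p = 0.33 with an estimated correlation), among them the collagen chains Col6a3 (-0.98) and Col3a1 (-0.63). Of endothelium and mural cell genes 4 of 15 members fell (11 lower adjusted over the list alone, median -0.39, camera adjusted p = 8.3e-16, adjusted p = 0.33 with an estimated correlation), among them the smooth muscle genes Myh11 (-0.85) and Acta2 (-0.63) and the pericyte receptor Pdgfrb (-0.69). The choroid plexus list, in which 8 members rose by day, had a median of -0.03 (0.12 relative to all genes), and 0 of 14 members passed the test (0 adjusted over the list alone, camera adjusted p = 0.0072, adjusted p = 0.66 with an estimated correlation). Without control pool 3 or cKO pool 2 its relative median was -0.194 and -0.138.

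Of 11936 genes 125 passed at ZT20, 1 higher and 124 lower. By limma on median-centred and on quantile-normalised values 0 passed, with 2695 and 963 at an unadjusted p under 0.05 against 1179 in the values as deposited; limma without a variance trend also gave 0 and trimmed-mean scaling gave 4. The median of all genes was -0.15 as deposited and 0.02 after quantile normalisation. The log2 ratio of the 3' to the 5' Actb control probe sets, a sign of RNA integrity, was higher in cKO (1.40 ± 0.08, SD, n = 3) than in control glands (1.19 ± 0.12), without overlap of the pools. The count was 427, 10 and 37 without control pools 1, 2 and 3, and 38, 43 and 463 without cKO pools 1, 2 and 3, of which 0 to 8 were higher. Without control pool 2 calls ended on Acta2, Adamts12, Aplnr, Cma1, Col6a3, Cpa3, Gad1, Mcpt4, Myh11, Pdgfrb and Sema3g (adjusted p 0.091 to 0.52) and without pool 3 on Col6a3, Myh11 and Pdgfrb (0.072 to 0.16). Without cKO pool 1 calls ended on Acta2, Adamts12, Aplnr, Col6a3, Cyp2f2, Myh11, Pdgfrb and Sema3g (adjusted p 0.054 to 0.37) and without pool 2 on Myh11 and Pdgfrb (0.063 to 0.065). That on Gad1 ended without pool 3 (adjusted p = 0.17). At both ZT6 and ZT20, which share a fit but no array, 34 genes were lower in cKO (1.51 expected of independent lists) and 1 higher. Fisher's exact test (p = 1.8e-37) takes genes as independent, but genes of the cell-type lists varied together.

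Averaged over both times, Mmp13 (-1.80 ± 0.18, adjusted p = 2.9e-14), Ibsp (-1.37), the osteoclast phosphatase Acp5 (-1.16 ± 0.18, adjusted p = 1.6e-06) and Tpsb2 (-1.14 ± 0.15, adjusted p = 5.1e-09) fell besides Neurod1 (-4.75 ± 0.24). Iglv1 (1.60 ± 0.20, adjusted p = 2.1e-09), Gad1 (1.35 ± 0.20, adjusted p = 2.7e-07), Igll1 (1.02), the protease Tmprss2 (0.73) and Stum (0.64) rose. Of choroid plexus genes 7 of 14 members rose (9 higher adjusted over the list alone, camera adjusted p = 6.0e-19, adjusted p = 0.46 with an estimated correlation). Of microglia and macrophage genes 6 of 17 members fell (12 lower adjusted over the list alone, camera adjusted p = 1.8e-09, adjusted p = 0.72 with an estimated correlation), including the complement component C1qb (-0.50). Of interferon and antigen presentation genes 1 of 18 members fell, the proteasome subunit Psmb8 (-0.58, 8 lower adjusted over the list alone, camera adjusted p = 6.7e-06, adjusted p = 0.99 with an estimated correlation). Among clock genes Per3 fell (-0.45 ± 0.12, adjusted p = 0.012). In total 382 genes passed (40 higher, 342 lower), 5201 after median centring (5029 and 172) and 195 after quantile normalisation (58 and 137, 120 shared). The count was 220 without control ZT6 pool 3, 702 and 249 without control ZT20 pools 1 and 3, and 254 without cKO ZT6 pool 3. It was 207 and 751 without cKO ZT20 pools 2 and 3, and 587 and 129 without both pools of residual Neurod1 signal and without both ZT6 pools of high Gnat1. Higher and lower genes numbered 6 and 337 without control ZT6 pool 1, 62 and 225 without control ZT6 pool 2, 69 and 204 without control ZT20 pool 2 and 80 and 269 without cKO ZT20 pool 1. Without control ZT20 pool 3 or cKO ZT20 pool 2, 13 were higher. Without control ZT6 pool 1 calls ended on Stum and Tmprss2 (adjusted p 0.058 to 0.074) and without pool 2 on C1qb, Psmb8 and Stum (0.064 to 0.085). Those on C1qb, Per3, Psmb8 and Tmprss2 ended without pool 3 (adjusted p 0.058 to 0.17). Without control ZT20 pool 2 calls ended on C1qb, Per3 and Psmb8 (adjusted p 0.064 to 0.075) and without pool 3 on C1qb, Psmb8 and Tmprss2 (0.053 to 0.13). Without cKO ZT6 pool 1 or 2 the call on Stum ended (adjusted p 0.057 and 0.088). Those on C1qb, Psmb8 and Tmprss2 ended without pool 3 (adjusted p 0.083 to 0.58). Without cKO ZT20 pool 2 calls ended on C1qb, Per3 and Tmprss2 (adjusted p 0.063 to 0.095) and without pool 3 on Stum and Tmprss2 (0.063 to 0.12). On quantile-normalised values calls ended for Acp5, Ibsp, Psmb8 and Tmprss2 (adjusted p 0.17 to 0.23). After median centring those on Per3 (-0.18, adjusted p = 0.055), C1qb (-0.24, adjusted p = 0.072) and Psmb8 (-0.32, adjusted p = 0.081) ended.

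Day and night were compared first within control pineal glands. At night Aanat rose by 3.01 ± 0.18, adjusted p = 2.8e-33, a mean signal of 4622 ± 1030 (SD) against 567 ± 164. Larger rises were in the G protein subunit Gng4 (4.25 ± 0.21, adjusted p = 1.9e-41), the cell-cycle repressor E2f8 (3.87 ± 0.22, adjusted p = 8.8e-37), carboxypeptidase Cpm (3.78 ± 0.24, adjusted p = 8.9e-31) and Tunar (3.69). Further ones were in Mctp2 (2.98), stanniocalcin Stc2 (2.92), Gulo, an enzyme of vitamin C synthesis (2.81), the potassium channel Kcnc1 (2.75) and Pgbd1 (2.59). Falls were led by Clca1 (-2.18 ± 0.25, adjusted p = 9.4e-13), relaxin Rln1 (-1.80), the phosphatase subunit Ppp2r2b (-1.71), Wdr17 (-1.69), Dpp10 (-1.68), the calcium channel subunit Cacnb2 (-1.68), contactin Cntn4 (-1.65), Kif26b (-1.63), Syndig1l (-1.53) and the clock repressor Nr1d1 (-1.46 ± 0.19, adjusted p = 4.5e-10). These 20 genes passed also on quantile-normalised values and whichever single pool was left out.

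Of the cAMP-responsive and night-induced list, the genes that noradrenaline drives in the pineal gland, 14 of 19 members rose (14 higher adjusted over the list alone, median 1.07, camera adjusted p = 2.7e-24, adjusted p = 0.061 with an estimated correlation), among them the nuclear receptors Nr4a3 (1.76) and Nr4a1 (1.40) and the phosphodiesterase Pde10a (1.52). Of core clock genes 3 of 22 members rose and 5 fell (5 higher and 5 lower adjusted over the list alone, camera adjusted p = 0.76): Cry1 (1.43) and Per1 (0.75) rose, and Nr1d1, Ciart (-1.07) and Dbp (-0.47) fell. Of rod photoreceptor genes, many of which pinealocytes also express, 1 of 29 members rose and 10 fell (1 higher and 11 lower adjusted over the list alone, median -0.26, camera adjusted p = 4.3e-06, adjusted p = 0.9 with an estimated correlation). The median was -0.113 without control ZT6 pool 3, where rod signals were high (Gnat1 3830 against 73 and 1266). Lower were the rod factor Nrl (-1.59), phosducin Pdc (-1.17) and the outer segment protein Prph2 (-0.79). Of cone genes 3 of 12 members fell (4 lower adjusted over the list alone, camera adjusted p = 0.0028, adjusted p = 0.9 with an estimated correlation), namely the opsin Opn1sw (-1.49 ± 0.22, adjusted p = 1.8e-08), Rxrg (-0.67) and the cone transducin Gnat2 (-0.41). In the pinealocyte list 4 of 23 members rose and 6 fell (4 higher and 9 lower adjusted over the list alone, camera adjusted p = 0.29), with rises of the adrenergic receptor Adra1b (1.51), the dopamine receptor Drd4 (1.38) and Crx (0.39) and a fall of Sag (-0.23), while Tph1 was at 0.07 ± 0.06 and Otx2 at -0.22 ± 0.09. In the bHLH list 1 of 13 members fell, Neurod4 (-0.35, 1 lower adjusted over the list alone, camera adjusted p = 0.33), and Neurod1 was at -0.47 ± 0.34. In all 1017 genes passed, 631 higher at night and 386 lower, 1839 after median centring (1092 and 747) and 3100 after quantile normalisation (1484 and 1616, 995 shared). The count was 629 (310 and 319) without control ZT6 pool 1 and 645 (381 and 264) without control ZT20 pool 3. Lower genes numbered 219 and 197 without control ZT6 pools 2 and 3 and 191 without control ZT20 pool 1. Without control ZT6 pool 1 calls ended on Dbp (adjusted p = 0.16) and without pool 2 on Dbp and Sag (0.071 to 0.12). Those on Dbp, Nrl and Prph2 ended without pool 3 (adjusted p 0.069 to 0.1). Without control ZT20 pool 1 calls ended on Dbp, Gnat2, Rxrg and Sag (adjusted p 0.055 to 0.32) and without pool 3 on Per1 (0.14). On quantile-normalised values Otx2 passed (adjusted p = 0.0045) and Nrl did not (adjusted p = 0.079), nor after median centring (adjusted p = 0.06).

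**Figure D3:**
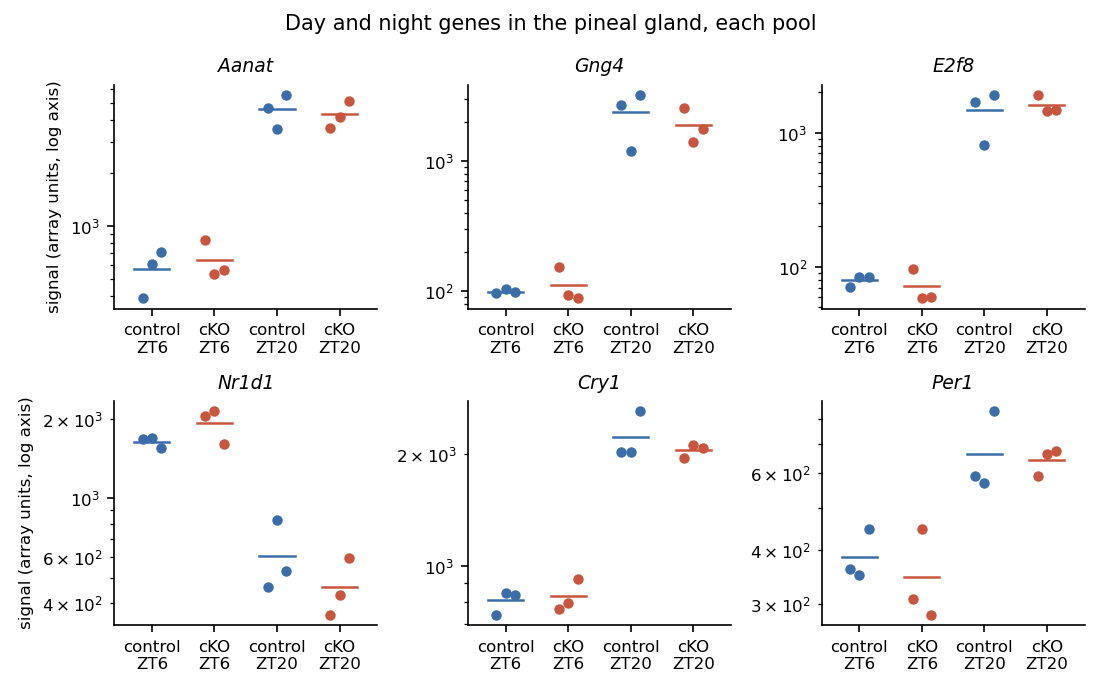
Signal of 6 genes that differed between day and night in control pineal glands, in every pool (points, log axis, array units) with the group mean (line). Aanat, Gng4, E2f8 and Cry1 are higher at ZT20 and Nr1d1 is lower in both genotypes.

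In cKO glands the same leading genes differed between day and night: E2f8 (4.24 ± 0.22, adjusted p = 6.7e-41), Gng4 (3.90 ± 0.21), Cpm (3.43 ± 0.24), Stc2 (3.12 ± 0.21) and Aanat (2.74 ± 0.18, adjusted p = 3.7e-29) rose. Clca1 (-2.82 ± 0.25), Ppp2r2b (-2.26), Cacnb2 (-2.20) and Cntn4 (-2.18) fell, as did Iglv1 (-2.66 ± 0.29). The lens crystallin Crygb rose (3.12 ± 0.45, adjusted p = 1.0e-08), but not on quantile-normalised values (adjusted p = 0.076) nor without cKO ZT20 pool 3 (adjusted p = 0.095). Dbp did not pass without cKO ZT6 pool 2 or cKO ZT20 pool 1 (adjusted p = 0.05 and 0.054). Of the cAMP-responsive list 15 of 19 members rose and 1 fell (15 higher and 1 lower adjusted over the list alone, median 1.2, camera adjusted p = 1.7e-32, kept at adjusted p = 0.025 with an estimated correlation), with Nr4a1 (1.80) and the cAMP-responsive factor Crem (1.42). In the core clock list 3 of 22 members rose and 3 fell (3 higher and 4 lower adjusted over the list alone, camera adjusted p = 0.89), with Nr1d1 (-2.06), Cry1 (1.29), Per2 (1.04), Per1 (0.89) and Dbp (-0.62). Of lens genes 4 of 6 members rose (5 higher adjusted over the list alone, camera adjusted p = 2.2e-10, adjusted p = 0.18 with an estimated correlation). Of immediate-early genes 4 of 10 members rose (4 higher adjusted over the list alone, camera adjusted p = 3.8e-06, adjusted p = 0.19 with an estimated correlation). Of rod genes 11 of 29 members fell (1 higher and 12 lower adjusted over the list alone, median -0.03, camera adjusted p = 0.013, adjusted p = 0.97 with an estimated correlation), and camera's call ended without cKO ZT6 pool 3 or cKO ZT20 pool 3 (adjusted p = 0.615 and 0.268). The call on Neurod1 at night in cKO (2.81 ± 0.34) came from the pools with residual signal: without them it was at -0.63. The Actb ratio was higher in cKO glands at ZT20 than at ZT6 (1.16 ± 0.11), again without overlap. In total 1369 genes passed (354 and 1015), 1651 after median centring (560 and 1091) and 2172 after quantile normalisation (1018 and 1154, 1191 shared). The count was 747 and 813 without cKO ZT6 pools 1 and 2, 753, 837 and 3221 without cKO ZT20 pools 1, 2 and 3 (278 to 365 of these higher), and 2950 without pools 2 and 3 together. Controls and cKO, which share a fit but no array here, had 290 genes higher at night in common (18.7 expected of independent lists) and 290 lower (32.8 expected). In cKO 2 and 3 passed the opposite way (53.7 and 11.4 expected).

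Whether the day-night difference itself depended on genotype was tested as an interaction. Neurod1 (3.27 ± 0.47), S100a8 (2.16 ± 0.33, adjusted p = 2.2e-06), Slfn4 (2.13), S100a9 (1.72) and the platelet chemokine Ppbp (1.69) had a higher night to day difference in cKO, and Iglv1 (-2.53 ± 0.41, adjusted p = 1.4e-05), Spry1 (-1.68), Kcnk3 (-1.59), Igll1 (-1.52) and Sema3g (-1.42) a lower one. The rhythmic genes did not pass: Aanat was at -0.27 ± 0.26 (adjusted p = 0.81), Per1 at 0.14 ± 0.28, Dbp at -0.14 ± 0.22 and Crx at -0.05 ± 0.10. Of cAMP-responsive and core clock genes 0 of 19 and 22 members passed (0 adjusted over the list alone in each, camera adjusted p = 0.15 and 0.33). Of rod genes 0 of 29 members passed the test (0 adjusted over the list alone), but their median was 0.14 above that of all genes (camera adjusted p = 0.013, adjusted p = 0.79 with an estimated correlation). Camera's call on them ended without control ZT6 pool 3, control ZT20 pool 3 or cKO ZT6 pool 1 or 2 (adjusted p 0.087 to 0.33). Of choroid plexus genes 5 of 14 members fell (11 lower adjusted over the list alone, camera adjusted p = 5.5e-15, adjusted p = 0.27 with an estimated correlation), with Kl at -1.02. By limma 43 genes passed (12 and 31), 2 after median centring (of those named Slfn4) and 0 after quantile normalisation, without a variance trend or after trimmed-mean scaling, with 798 as deposited and 1166 on quantile-normalised values at an unadjusted p under 0.05. Without control ZT6 pools 1 and 2 the count was 2 and 77, and without control ZT20 pools 1, 2 and 3 it was 88, 27 and 98. It was 27 and 75 without cKO ZT6 pools 2 and 3, and 27, 82 and 2 without cKO ZT20 pools 1, 2 and 3. Without control ZT20 pool 2, cKO ZT6 pools 1 and 2 and cKO ZT20 pool 1, 21, 13, 14 and 17 were higher and 6, 17, 13 and 10 lower. Of the genes named as called, each lost its call without control ZT6 pool 1 or cKO ZT20 pool 3 (adjusted p 0.053 to 1 over all pools that ended a call). Without the pools of residual Neurod1 signal 321 passed, and Neurod1 was at -0.16.

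In the retina at ZT6 cKO tissue had more transcript of glial reaction and of immune cells, and less of some photoreceptor genes. The largest rises were in the bHLH factor Tal2 (5.58 ± 0.34, adjusted p = 7.2e-08, or 7.0 and 4.09 with a pseudocount of 1 and 64, with control signals of 3.5 to 23.3), AF067061 (3.81), the noradrenaline transporter Slc6a2 (3.46 ± 0.23, adjusted p = 1.1e-07), the serine protease inhibitor Serpina3n (3.40 ± 0.40, adjusted p = 2.9e-05), the metalloproteinase inhibitor Timp1 (3.39), carboxylesterase Ces2b (3.35), A2m (3.19), lipocalin Lcn2 (3.08), Tcstv1 (3.05) and endothelin Edn2 (3.04). Besides Neurod1 the largest falls were in the disulphide isomerase Agr2 (-3.43 ± 0.31, adjusted p = 2.2e-06), Cldn23 (-2.80), the photoreceptor ankyrin repeat gene Ankrd33 (-2.75 ± 0.43, adjusted p = 4.0e-04), the vesicle release protein Doc2b (-2.51), St6galnac2 (-2.51), histidine decarboxylase Hdc (-2.49), Knstrn (-2.34), Dleu7 (-2.24) and Erich6 (-2.24). The medium-wave cone opsin Opn1mw fell (-1.93 ± 0.32, adjusted p = 7.1e-04) and the short-wave opsin Opn1sw rose (0.54 ± 0.09, adjusted p = 9.7e-04). The rod transducin Gnat1 (0.09 ± 0.07), Sag (0.09 ± 0.06) and Crx (-0.13 ± 0.08) did not pass, Crx being called lower on quantile-normalised values (adjusted p = 0.015) and after median centring (adjusted p = 0.014).

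Of the reactive gliosis and injury list 17 of 18 members rose (17 higher adjusted over the list alone), with a median 2.02 above that of all genes (camera adjusted p = 9.9e-21, adjusted p = 0.31 with an estimated correlation); Gfap, the intermediate filament of reactive glia, rose by 2.68 ± 0.27, adjusted p = 6.0e-06. Of microglia and macrophage genes 13 of 13 members rose (13 higher adjusted over the list alone, median 1.29, camera adjusted p = 2.4e-12, adjusted p = 0.44 with an estimated correlation), led by the complement genes C1qc (2.58), C1qb (2.25) and C1qa (2.14). Of interferon and antigen presentation genes 14 of 16 members rose (15 higher adjusted over the list alone, camera adjusted p = 1.2e-07, adjusted p = 0.56 with an estimated correlation), with Ifit1 (2.48), Gbp2 (2.33) and Psmb8 (1.84). Of Mueller glia genes 15 of 18 members rose (15 higher adjusted over the list alone, median 0.23, camera adjusted p = 7.8e-07, adjusted p = 0.56 with an estimated correlation), among them the potassium channel Kcnj10 (1.46) and the glial factor Sox9 (1.08). Of astrocyte genes 4 of 8 members rose (5 higher adjusted over the list alone, camera adjusted p = 0.011, adjusted p = 0.6 with an estimated correlation). Of rod genes 1 of 36 members rose and 3 fell (1 higher and 3 lower adjusted over the list alone), with a median of -0.36 relative to all genes (camera adjusted p = 1.6e-12, adjusted p = 0.56 with an estimated correlation); Aipl1, the chaperone of the photoreceptor phosphodiesterase, fell by most (-1.03). Of cone genes 4 of 14 members rose and 3 fell (4 higher and 5 lower adjusted over the list alone, median -0.39, camera adjusted p = 2.3e-04, adjusted p = 0.56 with an estimated correlation): cone arrestin Arr3 (-0.62) and the transducin subunit Gngt2 (-0.88) fell and Gnb3 rose (0.68). Of photoreceptor transcription factors 2 of 12 members rose and 2 fell (2 higher and 2 lower adjusted over the list alone, median -0.23, camera adjusted p = 0.0034, adjusted p = 0.64 with an estimated correlation), with Esrrb (-0.54) and Mef2c (-0.46) lower and Otx2 (0.34) higher.

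The lists of the other retinal neurons did not pass by camera. Of bipolar genes 4 of 18 members rose (4 higher adjusted over the list alone, camera adjusted p = 0.68), including the rod bipolar kinase Prkca (0.29 ± 0.09, adjusted p = 0.029). In the amacrine, horizontal and ganglion cell lists 5 of 11, 3 of 7 and 7 of 15 members rose (8, 3 and 8 higher adjusted over the list alone, camera adjusted p = 0.1, 0.63 and 0.32). Of immediate-early genes 7 of 11 members rose (8 higher adjusted over the list alone, camera adjusted p = 0.0048, adjusted p = 0.56 with an estimated correlation), with Egr2 (2.51), Atf3 (1.65) and Egr1 (1.21). In the neuroendocrine and islet list 9 of 19 members rose (9 higher adjusted over the list alone, camera adjusted p = 0.24), with the granule protein Ptprn (1.39). In the bHLH list 6 of 15 members rose and 1 fell (6 higher and 1 lower adjusted over the list alone, camera adjusted p = 0.7), with Neurog2 (0.72) and Id2 (0.72). Of lens genes 0 of 16 members passed the test (0 adjusted over the list alone) with a median of -1.27 (camera adjusted p = 5.8e-14, adjusted p = 0.56 with an estimated correlation). Of oligodendrocyte and myelin genes 1 of 4 members rose, too few for a set test (1 higher adjusted over the list alone). Of retinal pigment epithelium and melanocyte genes 2 of 14 members rose (0 adjusted over the list alone, camera adjusted p = 0.63).

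At ZT6 2857 of 11696 genes passed, 2723 higher and 134 lower in cKO. By scaling, 1598 passed after median centring (797 and 801) and 1976 after quantile normalisation (1139 and 837, 1273 shared), where the median of all genes was -0.02 and 0.02 in place of 0.29. Gnat1 and Sag, both at 0.09, lay below that median. The 3' to 5' Actb ratio was lower in cKO (log2 1.18 ± 0.06, SD, n = 3) than in control retinas (1.40 ± 0.16). Without control pool 2 the count was 1147, and without cKO pools 2 and 3 1200 and 1792. Lower genes numbered 84 and 63 without control pools 1 and 2 and 86 and 88 without cKO pools 1 and 3. Without control pool 1 calls ended on Gngt2 (adjusted p = 0.094) and without pool 2 on Gngt2, Id2, Mef2c, Neurog2 and Prkca (0.063 to 0.1). Those on Mef2c, Otx2 and Prkca ended without pool 3 (adjusted p 0.057 to 0.065). Without cKO pool 1 calls ended on Gngt2 (adjusted p = 0.054) and without pool 2 on Gngt2, Neurog2, Otx2 and Prkca (0.058 to 0.13). Those on Gngt2, Mef2c and Neurog2 ended without pool 3 (adjusted p 0.075 to 0.1). On quantile-normalised values calls ended for Neurog2 and Prkca (adjusted p 0.15 to 0.24). After median centring they also ended for Opn1sw, Otx2 and Id2, with Prkca at -0.016.

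**Figure D4:**
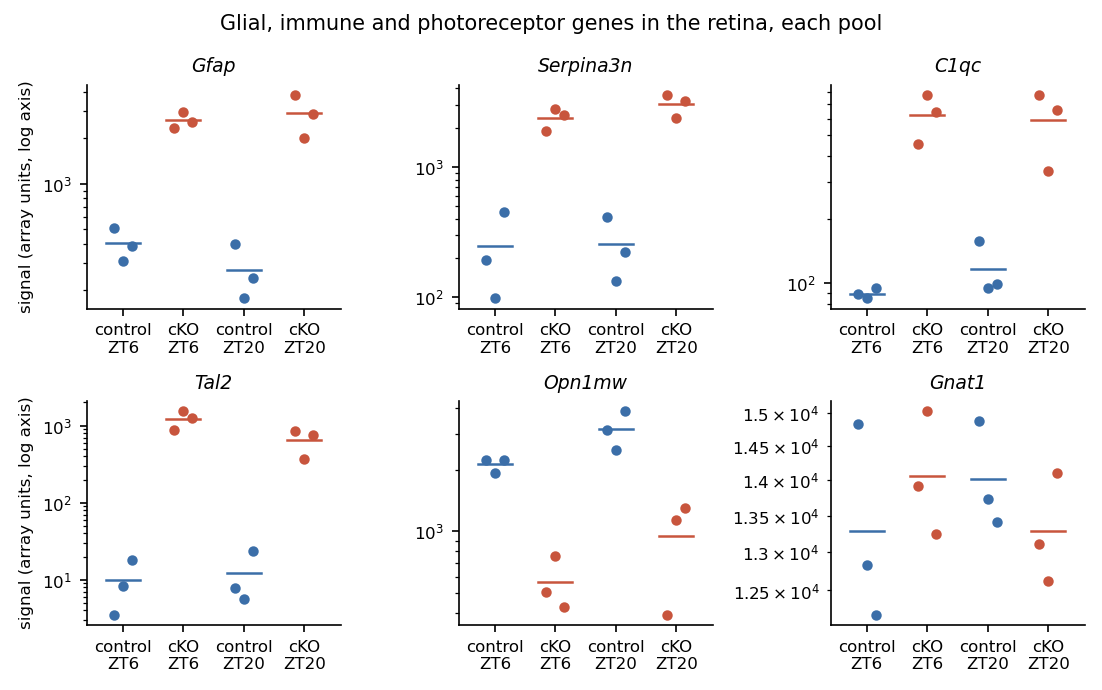
Signal of 6 genes in every retinal pool (points, log axis, array units) with the group mean (line). Gfap, Serpina3n, C1qc and Tal2 are higher and Opn1mw is lower in cKO at both times, and the pools of Gnat1 overlap.

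At ZT20 the retinal genotypes differed in many of the same genes. Tal2 (4.55 ± 0.34, adjusted p = 2.6e-07), AF067061 (4.13), Ces2b (4.07), Lcn2 (4.04 ± 0.33, adjusted p = 6.8e-07), Slc6a2 (4.0), Serpina3n (3.61), the immediate-early factor Egr2 (3.55), Gfap (3.37 ± 0.27, adjusted p = 6.1e-07), the melanosome gene Mlana (3.36 ± 0.94, adjusted p = 0.041) and the angiotensin receptor Agtr1a (3.34) rose most. Besides Neurod1, Ankrd33 (-2.39 ± 0.43, adjusted p = 0.0022), Hdc (-2.06), Doc2b (-2.0 ± 0.28, adjusted p = 1.8e-04), St6galnac2 (-1.94), Opn1mw (-1.88 ± 0.32, adjusted p = 0.0015), Agr2 (-1.78), BE949265 (-1.73), Cldn23 (-1.72) and Dleu7 (-1.64) fell most. Mlana did not pass on quantile-normalised values (adjusted p = 0.075) or after median centring (adjusted p = 0.064). Of reactive gliosis genes 18 of 18 members rose (18 higher adjusted over the list alone, median 2.08, camera adjusted p = 7.2e-34, adjusted p = 0.084 with an estimated correlation). Of microglia and macrophage genes 13 of 13 members rose (13 higher adjusted over the list alone, median 1.63, camera adjusted p = 2.1e-21, adjusted p = 0.12 with an estimated correlation). Of interferon genes 12 of 16 members rose (15 higher adjusted over the list alone, camera adjusted p = 3.5e-14, adjusted p = 0.24 with an estimated correlation). Of Mueller glia genes 6 of 18 members rose (12 higher adjusted over the list alone, camera adjusted p = 7.3e-07, adjusted p = 0.4 with an estimated correlation), with the apolipoprotein Apoe (0.88). Of rod genes 13 of 36 members fell (25 lower adjusted over the list alone, median -0.42, camera adjusted p = 1.1e-28, adjusted p = 0.17 with an estimated correlation), with Aipl1 (-0.96), Reep6 (-0.68), Rp1l1 (-0.63) and Impg1 (-0.58). Of cone genes 1 of 14 members rose and 4 fell (1 higher and 6 lower adjusted over the list alone, median -0.27, camera adjusted p = 5.0e-07, adjusted p = 0.3 with an estimated correlation), with Arr3 (-0.68) and the phosphodiesterase subunit Pde6h (-0.61). Of photoreceptor transcription factors 1 of 12 members fell, Nrl (-0.32, 5 lower adjusted over the list alone, camera adjusted p = 7.3e-07, adjusted p = 0.3 with an estimated correlation), while Crx was at -0.25 ± 0.08, Gnat1 at -0.08 ± 0.07 and Opn1sw at -0.11 ± 0.09. Crx passed as lower on quantile-normalised (adjusted p = 0.006) and median-centred values (adjusted p = 0.013).

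At this time 762 genes passed, 643 higher and 119 lower, 1264 after median centring (496 and 768) and 1226 after quantile normalisation (667 and 559, 660 shared), with medians of all genes of 0.12, -0.09 and 0.00. The Actb ratio was 1.30 ± 0.19 in cKO and 1.65 ± 0.16 in control retinas. Without control pool 2 the count was 383 and without cKO pool 1 279, and it was 536 without cKO pools 2 and 3, those with residual Neurod1 signal. Lower genes numbered 69 and 50 without control pools 1 and 3 and 34 without cKO pool 1. Without control pool 1 calls ended on Impg1, Neurod1 and Nrl (adjusted p 0.06 to 0.21) and without pool 2 on Impg1, Mlana and Neurod1 (0.062 to 0.22). Those on Impg1, Mlana, Neurod1 and Nrl ended without pool 3 (adjusted p 0.07 to 0.14). Without cKO pool 1 calls ended on Arr3, Impg1, Mlana, Nrl and Pde6h (adjusted p 0.056 to 0.29) and without pool 2 on Impg1 and Mlana (0.056 to 0.075). That on Mlana ended without pool 3 (adjusted p = 0.056). The comparisons at ZT6 and ZT20 share no array, and had 552 higher genes in common (150 expected of independent lists) and 69 lower ones (1.36 expected).

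**Figure D5:**
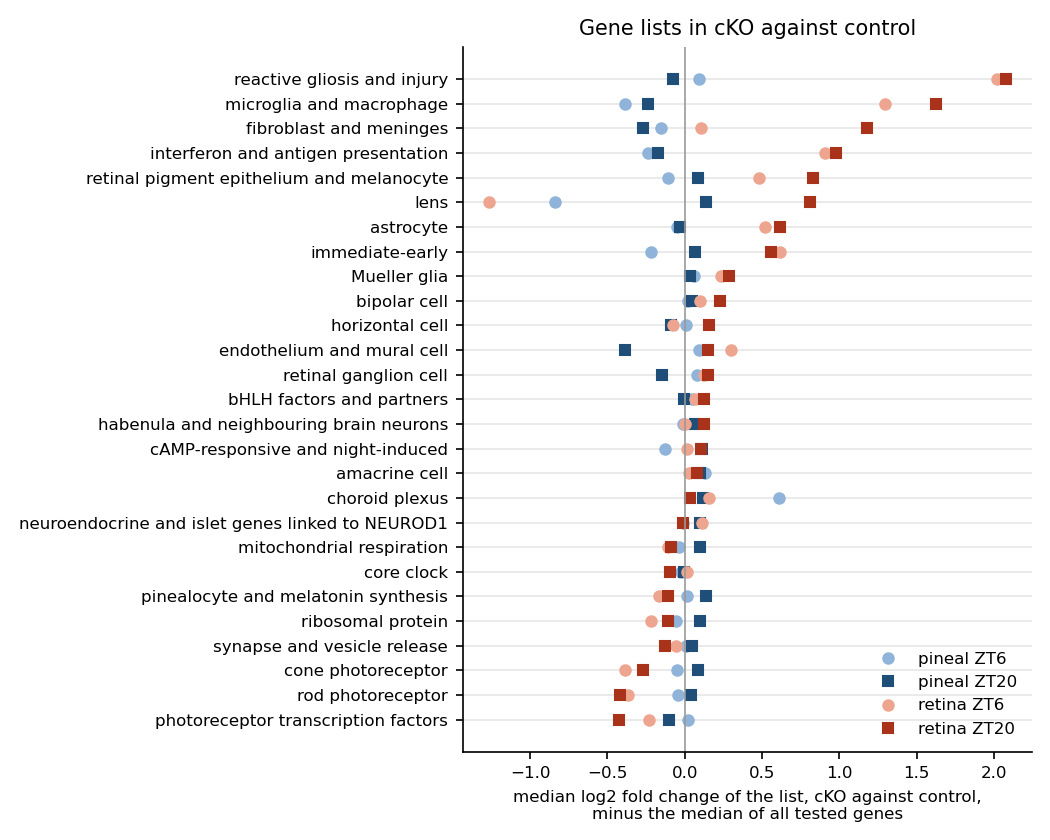
Median log2 difference of each gene list between cKO and control, less the median of all tested genes, in the pineal gland (blue) and retina (red) at ZT6 (circles) and ZT20 (squares), for the lists with at least 5 tested members in both tissues. The reactive gliosis list lies at 2.02 and 2.08 in the retina against 0.10 and -0.07 in the pineal gland, and the microglia list at 1.29 and 1.63 against -0.38 and -0.24.

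Averaged over both times in the retina, Tal2 (5.06 ± 0.24, adjusted p = 4.0e-10), AF067061 (3.97), Slc6a2 (3.73 ± 0.16, adjusted p = 2.2e-10), Ces2b (3.71) and Lcn2 (3.56) rose most. Agr2 (-2.61 ± 0.22, adjusted p = 2.5e-07), Ankrd33 (-2.57), Hdc (-2.28) and Cldn23 (-2.26) fell most besides Neurod1 (-2.82 ± 0.40). Crx fell by a small amount (-0.19 ± 0.05, adjusted p = 0.013). Of bipolar genes 10 of 18 members rose (12 higher adjusted over the list alone, camera adjusted p = 0.17), including Trpm1 (1.67), a channel of ON bipolar cells and also of melanocytes, whose Mlana rose at ZT20. Of rod genes 16 of 36 members fell (18 lower adjusted over the list alone, median -0.39, camera adjusted p = 6.8e-25, adjusted p = 0.22 with an estimated correlation), and 3537 genes passed in all (3264 higher and 273 lower, 1102 and 1808 after median centring, 1591 and 1395 after quantile normalisation). Without cKO ZT20 pool 1 the count was 2212, and the call on Trpm1 ended without control ZT6 pool 2, control ZT20 pool 2 or 3 or cKO ZT6 pool 3 (adjusted p 0.052 to 0.055) and on quantile-normalised and median-centred values (adjusted p = 0.08 and 0.075).

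Day and night differed in few genes of the control retina. Irf7, an interferon regulatory factor (2.20 ± 0.30, adjusted p = 0.0029), Pgbd1 (1.71), Drd4 (1.42), Adgrl4 (1.42), Ptpn20 (1.24), the water channels Aqp1 (1.14 ± 0.14, adjusted p = 0.0018) and Aqp4 (0.59), Impg1 (0.95), the salt-inducible kinase Sik2 (0.85 ± 0.11, adjusted p = 0.0018) and Ier3 (0.68) were higher at night. The stress hormone Crh (-1.50 ± 0.22, adjusted p = 0.0059), Glmn (-1.10 ± 0.14, adjusted p = 0.0019) and the deiodinase Dio2 (-1.09 ± 0.14, adjusted p = 0.0019) were lower. Per1 (0.08 ± 0.23) and Dbp (-0.04 ± 0.16) did not pass. In the core clock list 0 of 22 members passed the test (2 higher and 1 lower adjusted over the list alone, camera adjusted p = 0.99). The count was 16 (12 and 4), 92 after median centring (67 and 25) and 145 after quantile normalisation (81 and 64, 15 shared), and between 4 and 11 without 1 pool (9, 9 and 10 without control ZT6 pools 1, 2 and 3, 6 and 4 without control ZT20 pools 1 and 3). Aqp1, Sik2, Glmn and Dio2 passed whichever pool was left out, and the other called genes did not (adjusted p 0.051 to 0.24).

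In the cKO retina Pgbd1 (1.96 ± 0.30, adjusted p = 0.013), Wdr31 (0.80) and Sik2 (0.70) rose at night. Ly75 (-1.54), the collagen Col19a1 (-1.50) and Glmn (-1.20 ± 0.14, adjusted p = 0.0021) fell, 6 genes in all, with 26 after median centring (8 and 18) and 38 after quantile normalisation (15 and 23). Without cKO ZT6 pools 1 and 3 and cKO ZT20 pool 1 the count was 1, 2 and 10, and Glmn was the gene that passed whichever pool was left out (adjusted p 0.066 to 0.25 for the others). For a difference of the retinal rhythm between genotypes limma called 0 of 11696 genes, also after median centring, after quantile normalisation and without a variance trend, with 698 at an unadjusted p under 0.05 (936 after quantile normalisation), and trimmed-mean scaling called 2. Without control ZT20 pool 2 or cKO ZT20 pool 1 it called 1.

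The genotype effect was compared between the tissues as an interaction, averaged over both times. It was higher in the retina for Tal2 (5.04 ± 0.28, adjusted p = 3.4e-13), Lcn2 (4.21), Slc6a2 (4.03 ± 0.23, adjusted p = 3.4e-13), AF067061 (3.92), Timp1 (3.68) and Gfap (2.95 ± 0.25, adjusted p = 8.7e-10). It was lower there for Doc2b (-2.36 ± 0.28, adjusted p = 3.9e-07), Ankrd33 (-2.33), St6galnac2 (-2.16), Cldn23 (-2.11), Hdc (-2.08), Opn1mw (-1.56 ± 0.35, adjusted p = 0.0017) and Crx (-0.21 ± 0.07, adjusted p = 0.035, but -0.73, adjusted p = 9.0e-06 after median centring). Neurod1 was at 1.93 ± 0.80 (adjusted p = 0.082). Of reactive gliosis genes 18 of 18 members rose (18 higher adjusted over the list alone, median 2.27, camera adjusted p = 2.6e-33, kept at adjusted p = 0.0096 with an estimated correlation). Of microglia and macrophage genes 16 of 17 members rose (17 higher adjusted over the list alone, median 1.64, camera adjusted p = 2.8e-28, kept at adjusted p = 0.025 with an estimated correlation). Of rod genes, at a median of -0.39, 2 of 36 members fell (1 lower adjusted over the list alone, camera adjusted p = 3.0e-16, adjusted p = 0.12 with an estimated correlation). In all 2726 of 12866 genes passed (2635 and 91), 5193 after median centring (720 and 4473) and 2075 after quantile normalisation (1124 and 951, 1215 shared), with medians of all genes of 0.27, -0.25 and -0.02. Without the cKO ZT20 pools of residual Neurod1 signal 4218 passed, and without pineal cKO ZT20 pool 3 3974 were higher. The call on Crx ended without pineal control ZT6 pool 3 or ZT20 pool 2, pineal cKO pool 2 of either time, retina control pool 1 of either time, retina cKO ZT6 pool 3 or ZT20 pool 1 or 2 (adjusted p 0.05 to 0.077). Of genes tested in both tissues, 12 were higher in cKO in both (7.64 expected, Fisher's exact test, p = 0.055), 9 lower in both (4.38 expected, p = 0.032) and 1 and 72 of those higher and lower in the pineal gland passed the opposite way in the retina (0.598 and 55.9 expected).

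Control retina and control pineal gland were compared to describe the tissues. Cnga1, the rod cyclic nucleotide channel (7.03 ± 0.45, adjusted p = 1.3e-14), Rit2 (6.88), the homeobox gene Isl1 (6.76), Vax2os (6.76) and Fstl5 (6.69) were highest in the retina against the pineal gland. Spink4 (-7.45 ± 0.19, adjusted p = 9.8e-24), Cnpy1 (-7.29), Dlk1 (-7.21), Esm1 (-7.18) and the tachykinin Tac4 (-7.05 ± 0.14, adjusted p = 8.8e-26) were highest in the pineal gland. Tph1 (-6.48) and Aanat (-4.79) were higher in the pineal gland and Opn1mw (5.57), Gnat1 (4.45 ± 0.63) and Opn1sw (2.89) in the retina. Crx did not pass (-0.04 ± 0.05), but was called higher in the retina on quantile-normalised values (adjusted p = 0.0033). Of rod genes 31 of 36 members rose (31 higher adjusted over the list alone, camera adjusted p = 1.2e-16, adjusted p = 0.21 with an estimated correlation). Of bipolar genes 15 of 18 members rose and 2 fell (15 higher and 2 lower adjusted over the list alone, camera adjusted p = 2.5e-07, adjusted p = 0.21 with an estimated correlation). Of microglia and macrophage genes 17 of 17 members fell (17 lower adjusted over the list alone, camera adjusted p = 1.0e-06, adjusted p = 0.33 with an estimated correlation), read as higher or lower in the retina. Of 12866 genes 9570 passed (2969 and 6601, 4764 and 5093 after median centring, 4792 and 5486 after quantile normalisation).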

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

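Apart from counts of array splits and the test of pools mixed with tissue that kept Neurod1, tests in this part were chosen after the result was seen. Intervals are over genes, not pools, unless arrays are named.

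The pineal day-night difference depended on genotype, by the interaction term, in 43 genes. Night less day was higher in cKO for Neurod1 (3.27), S100a8 (2.16), Slfn4 (2.13), S100a9 (1.72) and Ppbp (1.69), and lower for Iglv1 (-2.53), Spry1 (-1.68), Kcnk3 (-1.59), Igll1 (-1.52) and Sema3g (-1.42). Of 100 splits of the 12 arrays 11 gave as many genes, so chance is not excluded for the count. The highest other, 5863, points to a sample structure besides genotype and time, array brightness not excluded. The effect of genotype differed between retina and pineal gland in 2726 genes. It was higher in the retina for Tal2 (5.04), Lcn2 (4.21), Slc6a2 (4.03), AF067061 (3.92), Timp1 (3.68) and Gfap (2.95), and lower for Doc2b (-2.36), Ankrd33 (-2.33), St6galnac2 (-2.16), Cldn23 (-2.11), Hdc (-2.08), Opn1mw (-1.56) and Crx (-0.21). Of 100 splits of genotype labels 2 gave as many, the real one and another with 6183. That share, under 0.05, concerns no effect in either tissue, not an equal effect in both.

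In both tissues the pools 2 and 3 labelled cKO at ZT20 kept part of the Neurod1 signal. A control pool under a cKO label is argued against, because the highest of the 4 values was 52.4% of the control mean. Retina carried into the pineal pools is argued against too: 30 transcripts far higher in the control retina stood at a median of 0.747% (interval 0.617 to 0.966) of their retinal level in pineal pool 2, where 26.2% would be needed, and at 0.645% in control glands. A mixture with tissue that kept Neurod1 was tested in the retina by where genes changed by the knockout at ZT6 lay between control (0) and ZT6 cKO (100). Raised genes lay at a median of 80.2 (interval 74.7 to 86.8) in pool 2 and 94.2 (87.5 to 102.9) in pool 3 and lowered genes at 77.6 (73.9 to 82.1) and 77.7 (73.3 to 83.5), where a plain mixture needed 50.3 and 50.5. All lie above that, which goes against a plain mixture. It stays open, because pool 1, with little Neurod1 signal, lay at 133 for raised and 103 for lowered genes where 94.9 was needed, a second Neurod1 probe set read 34.6 and 34.3% in place of 49.7 and 49.5%, and the interval of raised genes in pool 2 reached across the bound of 80 set for excluding it. Incomplete deletion in some of the pooled mice, the biological candidate explanation, would be such a mixture and is not separated from others by this test.

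In the values as deposited, several marrow, bone, mast cell and choroid plexus genes differed between pineal genotypes at ZT6. At ZT20 bone, mast cell, fibroblast and vessel genes did. The first 3 lists were written from these values, and no list tested passed with an estimated correlation. At ZT20 no gene passed after median centring or quantile normalisation. Tpsb2 and Acta2 stood at -0.99 and -0.53 after the latter. The fibroblast and meninges list at ZT20 goes against array brightness as the whole cause, at -0.32 (interval -0.51 to -0.21) on quantile-normalised values. The choroid plexus list goes against one common loss of neighbouring tissue, at 0.60 (interval 0.41 to 0.79) at ZT6. Genes of each list varied together, so neither cause is excluded. Neighbouring tissue that varied from pool to pool goes with the correlation of list members between pools of one group, 0.329 to 0.734 in the 6 lists, where 95% of random lists of each size lay under 0.118 to 0.227. An effect of genotype on these tissues stays open.

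In the retina at ZT6 far more genes were higher than lower in cKO. A brighter scan or scaling of the cKO arrays is argued against by the 18 hybridisation control probe sets, if added in equal amounts: they differed by -0.0307 (interval over arrays -0.20 to 0.14) where the median of all genes was 0.29. Whether more labelled RNA on these arrays or a broad rise of transcripts was the source was not tested, and scaling steps remove both alike. Whether a lower share of photoreceptors took part cannot be told apart: on quantile-normalised values rod genes had a median of -0.19, while bipolar genes stood at 0.0918 (interval 0.0024 to 0.231), amacrine and ganglion cell genes at 0.14 each and Mueller glia genes at 0.39. The bipolar interval spans the bound of 0.1 that would have decided. A response of glia to the knockout stays open as a biological explanation.

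For comparisons of 3 pools against 3 there are 10 splits of the arrays, too few for a share under 0.05. The real split of the pineal gland called 234 genes at ZT6 (highest other 10), 125 at ZT20 (highest other 5771, so 2 of the splits gave as many), 1017 between day and night in controls (4) and 1369 in cKO (1). The split with 5771 calls points to a structure of the ZT20 samples besides genotype, array brightness not excluded. At ZT6, where same-numbered pools deviated together, 4 splits parted as many pairs of equal number, and the others than the real one called 0 to 1 genes. In the retina the real split called 2857 at ZT6 (highest other 6), 762 at ZT20 (0), 16 between day and night in controls (5) and 6 in cKO (2). Over both times 3 of 100 splits gave as many as the 382 of the pineal gland (highest other 5389, again a structure). The retina's 3537 (2910) and the 9570 between control tissues (7963) were reached by 1 of 100 each. These shares are under 0.05. For the retinal difference of day-night differences all 100 splits gave at least its 0 genes (highest 3537), which decides nothing.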

How the results depend on the processing

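The settings listed above as added were chosen after the results were seen, and the others were planned. Over all alternatives, named genes kept their side of the threshold 5949 times, uncalled ones whatever their sign. They lost the call 737 times, gained it 28 and reversed 9, and for lists these were 9321, 644, 278 and 21. A pseudocount of 1 for all comparisons, and other settings where none is named, left the count within 1.5 times. Counts that moved by more follow in the order pineal ZT6, ZT20, both times, day-night in control, day-night in cKO and difference of day-night differences. The retina follows likewise. The array weights favour arrays close to their group, stricter filters test fewer genes and calls of at least 2-fold add a criterion; otherwise the cause was not tested. The filter left out genes under their array's median, which is where signal over background limits the comparisons.

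In the pineal gland, calls of at least 2-fold numbered 63, 20, 20, 212 and 229 for the first 5 comparisons. Median centring gave 4175, 0, 5201, 1839 for control day-night and 2 for the difference. Quantile normalisation gave 0 at ZT20, 195 over both times, 3100, 2172 and 0, and cyclic loess 0, 195, 2947, 2279 and 0. Without a filter 33, 0, 160, 862 (day-night in cKO) and 0 passed, and with the stricter filter 85, 55 and 119. Without a variance trend the counts were 43, 0, 172, 662, 823 and 0, and with array weights 937, 6913, 4670, 2080, 8017 and 2773. The probe set of largest variance gave 425, 57, 723 and, for the difference, 12. Trimmed-mean scaling gave 4 at ZT20, 2693, 2176 and 0. With the groups compared alone in the fit 508 and 48 passed at ZT6 and ZT20. Without the pools of residual Neurod1 signal 565 passed at ZT20, 587 over both times, 2950 in cKO day-night and 321 for the difference, and with quantile normalisation added 1, 11 and, for the difference, 0. Without the ZT6 pools of rod transcripts 83 passed at ZT6 and 129 over both times. Leaving out single pools gave 95 to 219, 10 to 463, 207 to 751, 629 to 1020, 747 to 3221 and 2 to 98.

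In the retina, calls of at least 2-fold numbered 497, 372, 423 and, for control day-night, 10. Median centring gave 1598, 1264, 92 and 26 (ZT6, ZT20, day-night in control and in cKO), quantile normalisation 1226, 145 and 38 and cyclic loess 1211, 204 and 34 (the last 3 of these). Without a filter 10 genes passed in control day-night, and with the stricter filter 355 at ZT20, 2216 over both times and 3 in cKO day-night. Without a variance trend the day-night counts were 8 and 3. For cKO day-night and the difference, a robust variance model, a pseudocount of 64 and the probe set of largest variance each gave 10 and 1. With array weights 4689 passed at ZT20, 5670 over both times, 1069 and 28 in day-night and 3 for the difference. Trimmed-mean scaling gave 1207 at ZT20, 116, 29 and, for the difference, 2, and the groups compared alone 91 and 21 for day-night. Without the pools of residual Neurod1 signal 10 passed for the difference, and with quantile normalisation added 11 in cKO day-night and 2 for the difference. Leaving out single pools gave 1147 to 3567, 279 to 818, 2212 to 4360, 4 to 11, 1 to 10 and 0 to 1. For the cKO effect between tissues, calls of at least 2-fold numbered 779, and the count was 5193 after median centring, 1507 with the stricter filter, 8402 with array weights, 4218 without the pools of residual Neurod1 signal, 1672 with quantile normalisation added and 2017 to 4059 without single pools. Between control tissues it was 4223 at 2-fold or more, 6345 with the stricter filter and 9226 to 9575 without single pools.

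With the pool number as a block, pineal ZT6 gave 293 genes in all 12 arrays and 521 in its own 6 (508 without it), and control retina day-night 10. It moved no other count by over 1.5 times, ended the calls of 8 named genes and 4 lists (at pineal ZT6 the lens list, adjusted p = 0.074) and added those of 5 lists. The blocked fit of the 6 pineal ZT6 arrays added calls of the amacrine (adjusted p = 0.032) and bHLH lists and changed no other. Every pool correlated best with its own number in 3 of 28 pairs of groups. How many pairs random numbering would give was not tested, so a shared number is neither shown nor excluded.

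Without the pools of residual Neurod1 signal, Neurod1 itself turned from higher to lower in the pineal gland, at -0.628 in cKO day-night and -0.16 in the difference (-0.514 and -0.007 with quantile normalisation). Prkca turned to -0.016 in the retina at ZT6 after median centring. Crx between control tissues turned to 0.225 after median centring, 0.118 after quantile normalisation, 0.193 by cyclic loess and 0.2 by trimmed-mean scaling. Among lists, it is camera's direction that turned, which need not follow the median relative to all genes printed here (as reported, 0.138 for lens genes at pineal ZT20 and -0.057 between tissues). The lens list turned at pineal ZT20 after median centring (0.138), without control ZT20 pool 3 (-0.746, single pools -0.77 to 0.75) and without the pools of residual Neurod1 signal (-1.101, and -1.12 with quantile normalisation), in the pineal difference (-0.264, the latter setting) and in the cKO effect between tissues (-0.057 after median centring and 0.599 with that setting). Choroid plexus turned at pineal ZT20 without control pool 3 or cKO pool 2 (-0.138, single pools -0.194 to 0.314), and the cAMP-responsive list there without control pool 2 (single pools -0.007 to 0.179). Over both times in the pineal gland ribosomal protein genes turned after median centring (0.014), mitochondrial genes by cyclic loess (-0.05) and the bHLH list without a filter (0.038, and 0.104 at ZT20). In cKO retina day-night, photoreceptor transcription factors and pinealocyte genes turned without the pools of residual Neurod1 signal (-0.076 and -0.032, and -0.075 and -0.026 with quantile normalisation), and pigment epithelium genes turned in the retinal difference with quantile normalisation added (0.221). By fry, immediate-early (-0.08) and oligodendrocyte genes (-0.286) between control tissues went the other way from camera.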

Other observations

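These values were looked up after the comparisons had been seen and test no explanation.

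In the cKO retina at ZT20 further groups differed that the comparisons do not describe. Of immediate-early genes 6 of 11 members rose (6 higher adjusted over the list alone, camera adjusted p = 7.7e-06, adjusted p = 0.24 with an estimated correlation), with Egr3 (2.14) and Atf3 (1.80). Of fibroblast and meninges genes 3 of 10 members rose (4 higher adjusted over the list alone, camera adjusted p = 0.0017, adjusted p = 0.52 with an estimated correlation), with the matrix protein Fmod (1.92) and the growth factor receptor Pdgfra (1.33). Of retinal pigment epithelium and melanocyte genes 5 of 14 members rose (7 higher adjusted over the list alone, camera adjusted p = 0.083), with the melanosome genes Pmel (3.16) and Tyrp1 (2.48), and on quantile-normalised values neither of these passed (adjusted p = 0.057 and 0.066). The call on Fmod ended without control ZT20 pool 2 or 3 or cKO ZT20 pool 1 or 3 (adjusted p 0.053 to 0.16), that on Pmel without control pool 2 or 3 or cKO pool 1 (adjusted p 0.072 to 0.15), and that on Tyrp1 without these or cKO pool 2 (adjusted p 0.055 to 0.18) and after median centring (adjusted p = 0.062). The Mlana signal was 117, 124 and 1952 in control pools at ZT6 and 1508, 83 and 241 at ZT20, against 623, 393 and 2769 and 3138, 4273 and 3059 in cKO. Averaged over both times the granule protein Ptprn rose (1.42 ± 0.17, adjusted p = 1.1e-05) in the cKO retina and Cacna1f, the calcium channel of photoreceptor synapses, fell (-0.53 ± 0.15, adjusted p = 0.013).

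The Tal2 signal was 658 to 1356 in the 12 pineal pools of both genotypes, 3.5 to 23.3 in the 6 control retinal pools, around the 16 units added, and 365 to 1542 in the 6 cKO retinal pools.

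Rod transcripts varied between pineal pools of one group. The Gnat1 signal was 73, 1266 and 3830 in control pools at ZT6, 115, 77 and 2234 in cKO at ZT6, 958, 732 and 172 in control at ZT20 and 151, 447 and 620 in cKO at ZT20.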
